A study of Rattus norvegicus with 20 samples.

How the data were processed

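Total RNA of rat gastric ECL cells, PC cells and mucosal scrapings was labelled with Cy3 or Cy5 after linear amplification and hybridised to Agilent rat arrays, per the labels. The 20 samples are single dye channels of 11 arrays: ECL fed (3 samples, 1 Cy3 and 2 Cy5), ECL fasted (3, 2 Cy3 and 1 Cy5), PC fed (3, 1 Cy3 and 2 Cy5), mucosa fed (5, 2 Cy3 and 3 Cy5) and mucosa fasted (6, 3 of each dye). Groups and replicate numbers follow the labels.

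Per the file headers, the scanner files hold the mean intensity of each spot and the median intensity of its local background on a linear scale, extracted by the authors with Agilent Feature Extraction A.7.5.1, or with version 8.5.1.1 for the 3 arrays of the last extraction day. The same files hold processed signals that the scanner software had background-subtracted, detrended and dye-normalized within the array. The deposited series table holds, on the same linear scale, the processed intensity of each sample's own dye, with medians from 546.225 to 817.995 and no normalization between arrays. These statements were checked on the values: in each column of that table at least 99.986% of features were within rounding of the processed signal of its sample. For 6 arrays the scanner values are rounded to 3 significant digits. Extraction dates in the headers divide the arrays into 7 days, and only day 7 holds fed and fasted mucosa together.

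Scanner intensities were background-corrected with normexp (offset 50), log2-transformed, loess-normalized within arrays and scaled between arrays with Aquantile in limma 3.58.1 (statmod 1.5.0, R 4.3.3), with Python 3.11.15 for reading files and drawing figures. Control spots and spots marked as outliers by the scanner software were left out, and spots of 1 probe were averaged. Probes had to be well above background in at least 3 of the 20 samples. A gene with several probes was represented by the one with the highest mean, and a probe without a gene name was tested as itself, which gave 36218 features (16695 genes and 19523 unnamed probes). The share of spots well above background was 92.37% to 97.39% per sample, and the number of arrays limits precision. Where the probe was saturated in every sample of the higher group or not well above background in any sample of the lower group, the fold is given as a lower bound. Where the probe was saturated in every sample of the lower group, or in every sample of 1 group in the difference of both fasting effects, the results give neither fold nor difference.

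A single limma model held all 20 samples with group and dye as fixed terms and the array as a random block (correlation of the 2 channels of an array 0.8907, 14 residual degrees of freedom). The 6 contrasts were tested with moderated statistics, and features past a Benjamini-Hochberg adjusted p of 0.05 over all features were called higher or lower. The block gives most weight to differences between samples on 1 array, so that fitted differences can depart from differences of group means. Tests are two-sided. The 32 gene lists, each with at least 5 measured members, were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a contrast. With an estimated correlation 14 of the 102 calls of lists remained: mucosal fasting kept cell cycle, the difference of both fasting effects kept other endocrine markers and heat shock genes, ECL against PC cells kept other endocrine markers, PC cells against mucosa kept heat shock and cell cycle genes, and ECL cells against mucosa kept 8 lists given in the results. Fry, which asks whether a list's genes moved on balance in 1 direction and does not compare them with other genes, called 21, 23, 22, 26, 24 and 28 lists in the 6 contrasts.

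The lists cover markers of ECL, parietal, chief, surface and neck mucous, other endocrine, mast, immune, smooth muscle and stromal, endothelial, erythroid, squamous, and enteric neuron and glial cells. They also cover exocytosis, receptors, feeding-related peptides, fatty acid oxidation, cholesterol biosynthesis, lipogenesis, glycolysis, oxidative phosphorylation, glucocorticoid response, FOXO targets, circadian clock, immediate early genes, heat shock, endoplasmic reticulum stress, amino acid response, cell cycle, ribosomal proteins, proteasome, autophagy, and interferon response. Named genes are the 10 with the largest positive and the 10 with the largest negative difference among called genes with the probe well above background in every sample of a group and no overlap between the groups' samples (5 and 5 without the overlap criterion for the difference of both fasting effects). Up to 4 called members of each list and Hdc, Slc18a2, Chga, Cckbr, Atp4a and Atp4b in every contrast were added. Some genes that met this rule are not reported here.

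Values within batches were computed on arrays or days that held both groups, and for ECL cells of day 1 relative to the mucosa on the same arrays. The fit was tested on simulated data with the same design. Without change at most 1 of 12000 simulated genes was called. Of 200 genes planted at 2-fold between 189 and 200 were found per contrast, and 24 to 45 of 11400 unplanted genes were called. The simulated genes were independent, with 1 common array correlation and no effect of day. This test therefore covers the fit under its own assumptions and gives no rate of false calls for the real data. Alternatives covered background and scaling, the deposited table, the filter on dim probes, the dye term, the array block, a replicate block, the extraction day, the samples in the fit, probes, prior variance, sample weights and each sample left out. The channels beside ECL fed sample 1 and ECL fasted sample 3, which the labels do not describe, entered the normalization of their arrays only and no comparison.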

Results

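RNA from 3 kinds of rat stomach sample was hybridised to 11 Agilent 2-colour arrays. Enterochromaffin-like (ECL) cells are the histamine-storing endocrine cells of the acid-secreting mucosa. A second purified preparation is called PC cells in the labels, which do not expand the name, and the other kind of sample was scraped gastric mucosa. The rats had free access to food or had been without it for 24 h. There were 3 ECL samples from fed rats, 3 ECL samples from fasted rats, 3 PC samples from fed rats, 5 mucosal samples from fed rats and 6 mucosal samples from fasted rats. The labels give a purity of 95% for ECL cells and 99% for PC cells. Each sample was 1 dye channel of an array, so that 9 arrays held 2 samples each, and 2 arrays held 1 ECL sample beside a channel that the labels do not describe.

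Each array carried 41372 spots other than controls, and between 92.37% and 97.39% of them were well above background in each of the 20 samples. Median spot signals ran from 156 to 411.7 scanner units, and median local backgrounds from 24 to 47. The tests covered 36218 features, of which 16695 were named genes and 19523 were probes without a gene name. The number of arrays limits the precision of every value. Between 15 and 216 spots per sample lay at the top of the scanner's range, and a fold that rests on such spots is given as a lower bound, or not at all where every sample of the lower group was affected. Differences below are log2 differences from a linear model with their standard errors (SE), and group means are log2 intensities with their standard deviations (SD). Gene lists and the rule for naming genes were chosen before the data were examined.

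The first comparison asks what 24 h without food changed in ECL cells, the question in the title of the series. Ech1, an isomerase of fatty acid breakdown, was 5.06-fold higher in ECL cells of fasted rats, a difference of 2.34 ± 0.28 (SE; 13.08 ± 0.22 against 10.88 ± 0.12, mean ± SD, n = 3 and 3). Eci1 (3.33-fold) and the acyl-CoA thioesterase Acot2 (3.3-fold) rose too. Of 35 measured genes of fatty acid oxidation and PPAR alpha targets, 26 rose, 1 fell and 8 did not pass, with 26 higher and 1 lower adjusted over the list alone. The list median was 0.92 (adjusted p = 2.44e-18, and adjusted p = 0.0636 with an estimated correlation). Its median was 0.94 on array 4, the array that held both food groups, 0.88 on day 1 relative to the mucosa on the same arrays, and 0.60 between days 2 and 4. Parietal cell markers moved the same way in these samples: 8 of 18 rose, 1 fell and 9 did not pass, with a median of 0.35 (adjusted p = 0.00227, and adjusted p = 0.307 with an estimated correlation).

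Genes of sterol synthesis moved the other way. Of 25 cholesterol biosynthesis genes, 17 fell, none rose and 8 did not pass (median -0.47, adjusted p = 1.45e-08, and adjusted p = 0.158 with an estimated correlation). Hmgcs1, which feeds the mevalonate pathway, was 2.23-fold lower, and the isomerase Idi1 was 1.78-fold lower. The desaturases Scd2 and Scd were 3.36-fold and 2.15-fold lower, and Srebf1, a transcription factor of lipid synthesis, was 2.04-fold lower. The lipogenesis list did not pass, with 5 members higher and 6 lower, and its median of 0.05 differed in sign from its mean of -0.15.

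Among ECL cell markers, 9 of 19 fell, 2 rose and 8 did not pass (median -0.28, adjusted p = 0.00554, and adjusted p = 0.438 with an estimated correlation). The median was -0.10 on array 4, -0.25 on day 1 relative to the mucosa and -0.91 between days 2 and 4. Slc18a2, the transporter that loads histamine into vesicles, was 1.83-fold lower, at 12.35 ± 1.17 against 13.90 ± 0.24 (SD, n = 3 and 3). Slc18a1 (2.01-fold), the granule protein Scg3 (2.16-fold) and the transcription factor Neurod1 (1.88-fold) were lower as well. For chromogranin A (Chga) and for Hdc, the enzyme that makes histamine, spots were saturated in all 3 fed samples, so that no difference between fasted and fed rats can be given. The gastrin receptor Cckbr did not pass, at -0.24 ± 0.11 (SE, adjusted p = 0.122).

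Hormone genes of other gastric endocrine cells were lower in the ECL samples of fasted rats, with 5 of 10 lower and 5 not past the test (median -0.54, adjusted p = 2.01e-04, and adjusted p = 0.0636 with an estimated correlation). The median was -0.35 on array 4, -0.80 on day 1 relative to the mucosa and -0.13 between days 2 and 4, and that of cholesterol biosynthesis -0.50, -0.39 and -0.18. Somatostatin (Sst) fell 2.58-fold and Tph1, the serotonin-synthesising enzyme, fell 2.40-fold. The feeding-related peptides Cartpt and Nucb2 were 2.16-fold and 1.68-fold lower and the vesicle protein Rab3c 2.27-fold lower, although the lists they belong to did not pass.

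Markers of other stomach cells also differed between the ECL samples of fasted and fed rats. The parietal cell genes Atp4a (3.26-fold), Clic6 (2.61-fold) and Kcnq1 (2.60-fold) were higher in fasted rats, and Atp4b, the other proton pump subunit, was at least 2.09-fold higher. Of 13 surface and neck mucous cell markers 6 rose and 2 fell, with Gkn1 2.82-fold and Muc5ac 2.51-fold higher (median 0.40, adjusted p = 0.0381, and adjusted p = 0.438 with an estimated correlation), a call that was lost with extraction day in the fit (median 0.26). Chief cell markers had 4 of 10 members lower and 1 higher, among them Rnase1 (1.68-fold lower) and Cblif (1.64-fold lower), with a median of -0.33 (adjusted p = 0.0429, and adjusted p = 0.438 with an estimated correlation). Squamous forestomach markers had 7 of 14 members lower and none higher, with Sprr1a 2.26-fold and Sbsn 1.92-fold lower (median -0.32, adjusted p = 0.0012, and adjusted p = 0.307 with an estimated correlation).

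Heat shock, immediate early, glucocorticoid response and autophagy genes were higher in ECL samples of fasted rats. In fed rats the autophagy and oxidative phosphorylation lists were lower in ECL than in PC cells. The immediate early and glucocorticoid response lists were higher there, and the heat shock list did not pass. Heat shock and chaperone genes had 12 of 18 members higher and none lower, with Bag3 1.79-fold higher (median 0.42, adjusted p = 1.28e-04, and adjusted p = 0.0636 with an estimated correlation). Immediate early genes had 12 of 28 members higher and none lower, with Dusp5 2.25-fold and Junb 2.01-fold higher (median 0.37, or 0.24 with extraction day in the fit, adjusted p = 2.65e-04, and adjusted p = 0.307 with an estimated correlation). Glucocorticoid response genes had 6 of 18 members higher and 1 lower, with the kinase Sgk1 1.81-fold higher (median 0.21, adjusted p = 0.0199, and adjusted p = 0.239 with an estimated correlation). In the autophagy and lysosome list 12 of 27 genes rose and 2 fell, with Gabarapl1 2.31-fold and Sqstm1 1.69-fold higher (median 0.24, adjusted p = 0.00115, and adjusted p = 0.221 with an estimated correlation). Oxidative phosphorylation genes had 16 of 40 members higher and none lower, with Atp5f1a 1.90-fold higher (median 0.30, adjusted p = 7.61e-05, and adjusted p = 0.438 with an estimated correlation), but the median turned to -0.07 when only the ECL samples were fitted, and it was 0.42 on array 4, 0.36 on day 1 relative to the mucosa and -0.60 between days 2 and 4.

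Genes of growth and protein handling were lower in ECL samples of fasted rats. Against PC cells, ECL cells of fed rats had medians of 0.47 for the cell cycle, 1.02 for endoplasmic reticulum stress and 0.19 for ribosomal proteins. The median for the proteasome was -0.24. With fasting the proteasome list thus moved away from the PC level, and the others towards it. Cell cycle genes had 18 of 33 members lower and 3 higher, with Cdk1 2.54-fold and Ccna2 2.33-fold lower (median -0.41, adjusted p = 1.61e-06, and adjusted p = 0.118 with an estimated correlation). Endoplasmic reticulum stress genes had 10 of 21 members lower and 2 higher, with Sdf2l1 2.05-fold and Pdia3 1.78-fold lower (median -0.40, adjusted p = 0.00137, and adjusted p = 0.307 with an estimated correlation). Cytosolic ribosomal proteins had 25 of 73 members lower and 4 higher, with Rps9 1.49-fold lower (median -0.16, adjusted p = 2.65e-04, and adjusted p = 0.517 with an estimated correlation). Proteasome subunits had 8 of 24 members lower and none higher, with Psmb5 1.30-fold lower (median -0.15, adjusted p = 0.0178, and adjusted p = 0.474 with an estimated correlation). Between days 2 and 4 the medians were -0.02 for the cell cycle, -0.10 for endoplasmic reticulum stress, -0.03 for ribosomal proteins and -0.42 for the proteasome, against -0.41, -0.39, -0.17 and -0.17 on array 4 and -0.42, -0.29, -0.17 and -0.19 on day 1 relative to the mucosa.

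Outside the lists, the gluconeogenic enzyme Fbp1 rose 7.46-fold in ECL cells of fasted rats, Rab15 rose 4.77-fold, the growth factor Gdnf 4.20-fold, the carbonyl reductase Cbr1 4.18-fold and Zxdc 4.09-fold. Rtn4rl2 and Sh3bp5l rose 3.56-fold and 3.46-fold. The collectrin gene Cltrn fell 4.31-fold, thrombomodulin (Thbd) 3.39-fold, the kallikrein Klk1b3 3.09-fold and Serpinb3 2.88-fold. Dscc1 (2.81-fold), Pkig (2.80-fold), the gap junction gene Gja1 (2.77-fold), Taok2 (2.74-fold) and Ppia-ps12 (2.68-fold) were also lower. Of these, Fbp1 was lower and Klk1b3 higher in ECL than in PC cells of fed rats. For the others that difference is not given. Whether these genes changed within ECL cells, or the preparations differed in their cells, was not tested. Markers of mast cells (median 0.02), immune cells (-0.04), smooth muscle and stroma (0.01), endothelium (-0.02), erythroid cells (0.01) and enteric neurons and glia (-0.04) did not pass as lists. Neither did exocytosis genes (median 0.05), receptors (-0.03), feeding-related peptides (-0.12), glycolysis (0.14, a list that passed with extraction day in the fit), FOXO targets (0.07), circadian clock genes (0.02), the amino acid response (-0.03) or the interferon response (0.10). For smooth muscle, endothelium, exocytosis and lipogenesis the median, the mean and the direction of the test differed in sign.

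In total 8882 of 36218 features passed in ECL cells (4399 higher and 4483 lower), of which 299 were more than 2-fold higher and 132 more than 2-fold lower. Of the 32 lists 17 passed with the preset correlation, and with an estimated correlation the smallest adjusted p was 0.0636. Adjusted over the list alone, 29 ribosomal protein genes were lower in place of 25 and 19 oxidative phosphorylation genes higher in place of 16, and no other list shifted by more than 2. Treating the 2 channels of an array as independent left 727 features past the test, and leaving out ECL fasted sample 2, one of the pair on array 4, left 3621.

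**Figure D1:**
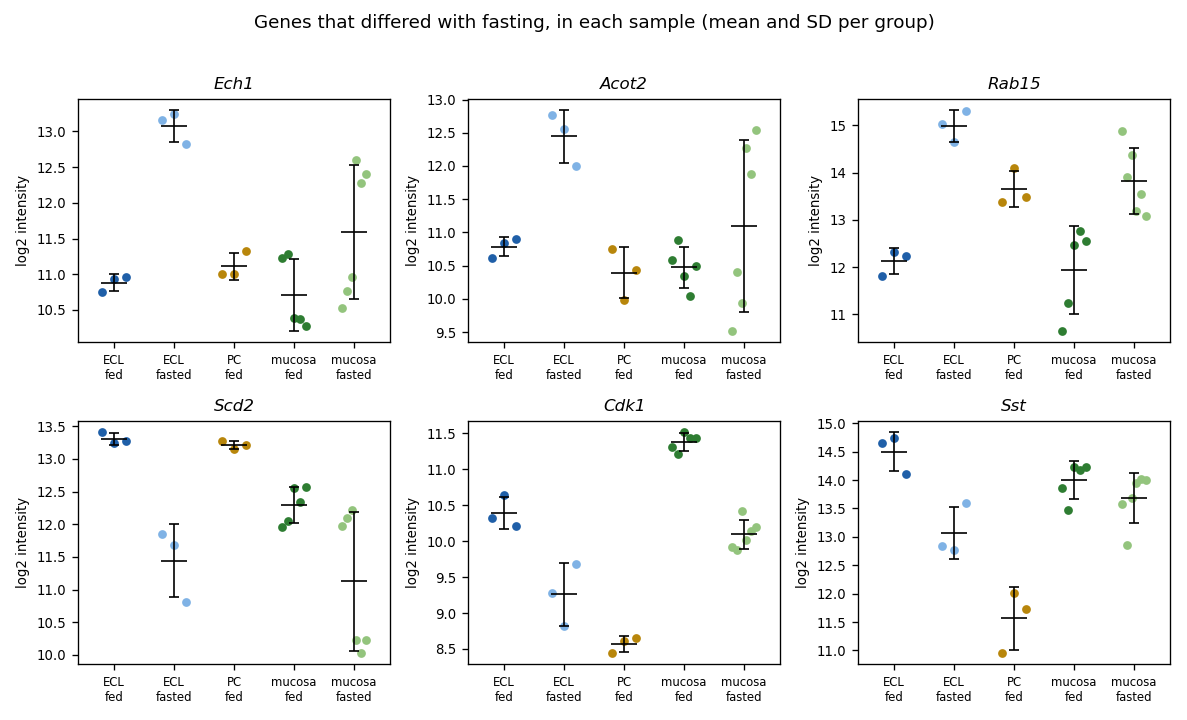
Log2 intensity (vertical axis) of 6 genes in each sample of ECL cells and mucosa from fed and fasted rats, with dots for samples and bars for the group mean and SD. Ech1 lay at 13.08 ± 0.22 in fasted and 10.88 ± 0.12 in fed ECL samples (SD, n = 3 and 3).

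The second comparison asks the same of the whole mucosa. Genes of dividing cells fell: 26 of 33 cell cycle genes were lower, 2 were higher and 5 did not pass (median -0.69, adjusted p = 3.24e-12). This call held with an estimated correlation, at an adjusted p of 0.0477. Pcna, the sliding clamp of DNA replication, was 2.95-fold lower, a difference of -1.56 ± 0.10 (SE; 10.68 ± 0.55 against 11.84 ± 0.15, mean ± SD, n = 6 fasted and 5 fed). Ccna2 (2.68-fold), Bub1 (2.64-fold), Aspm (2.62-fold), Ttk (2.59-fold), Pbk (2.57-fold), Ckap2 (2.54-fold), Rfc4 (2.50-fold) and Cdk1 (2.48-fold) were lower as well, and Dscc1, a factor that loads the clamp, was 3.31-fold lower. The median of the list was -0.71 on day 7, when each of 3 arrays held a fed and a fasted sample, and -0.63 between the samples of the other days, where food group and day cannot be told apart.

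Genes of protein handling, stress and cholesterol synthesis fell too. Endoplasmic reticulum stress genes had 19 of 21 members lower and none higher, with Creld2 2.23-fold and Pdia3 2.14-fold lower (median -0.65, adjusted p = 4.21e-10, and adjusted p = 0.0587 with an estimated correlation). Proteasome subunits had 22 of 24 members lower and none higher, with Psma2 1.60-fold lower (median -0.42, adjusted p = 8.81e-10, and adjusted p = 0.134 with an estimated correlation). Cholesterol biosynthesis had 21 of 25 members lower and 1 higher, with Idi1 2.43-fold lower (median -0.65, adjusted p = 4.21e-10, and adjusted p = 0.134 with an estimated correlation). Amino acid response genes had 9 of 17 members lower and 1 higher, with Psph 2.15-fold and Trib3 1.51-fold lower (median -0.16, adjusted p = 0.0212, and adjusted p = 0.544 with an estimated correlation). Heat shock genes had 7 of 18 members lower and none higher, with Hsph1 1.98-fold and Dnaja1 1.61-fold lower (median -0.18, adjusted p = 0.041, and adjusted p = 0.278 with an estimated correlation), a call that was lost with extraction day in the fit (median -0.16). On day 7 and on the other days these medians were -0.67 and -0.48 for endoplasmic reticulum stress, -0.44 and -0.47 for the proteasome, -0.64 and -0.42 for cholesterol, -0.22 and -0.44 for heat shock, and -0.20 and 0.07 for the amino acid response, which lay below 0 on day 7 alone.

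Fatty acid oxidation genes rose in mucosa, with 25 of 35 members higher, 1 lower and 9 not past the test (27 higher adjusted over the list alone), a median of 0.44 and an adjusted p of 1.96e-07 (adjusted p = 0.278 with an estimated correlation). Ech1 was 3.45-fold and Acot2 3.12-fold higher, while Scd2 was 4.05-fold lower and Srebf1 2.10-fold lower. This rise belonged to the samples of day 7, where the list median was 0.49 against -0.18 between the other days. Ech1 differed by 2.09 on day 7 and by -0.51 between the other days, Acot2 by 1.93 and -0.78, and Scd2 by -2.33 and 0.09. Txnip, a target of FOXO transcription factors, was 2.43-fold higher in the fit and behaved alike, at 1.61 and -1.08, while Foxo1 was 1.83-fold higher. Squamous forestomach markers had 12 of 14 members higher and none lower (median 0.78, adjusted p = 1.68e-06, and adjusted p = 0.144 with an estimated correlation), with a median of 0.90 on day 7 and 0.12 between the other days. Krt13 was 2.84-fold and Krt1 2.32-fold higher in the fit, but Krt13 differed by 2.02 on day 7 and by -2.27 between the other days, and Krt1 by 1.49 and -0.74.

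Endocrine genes of the mucosa moved in different directions. Gast, which encodes gastrin, rose 1.99-fold (difference 0.99 ± 0.09, SE; 0.94 on day 7 and 1.56 between the other days), and Ghrl, which encodes ghrelin, rose 1.45-fold. Slc18a2 fell 1.86-fold, Hdc 1.45-fold and Nucb2 2.11-fold, whereas Chga (0.20 ± 0.22, SE, adjusted p = 0.473) and Cckbr (0.12 ± 0.07, SE, adjusted p = 0.194) did not pass. Parietal cell markers had 11 of 18 members lower and 2 higher, with Kcnj16 1.80-fold and Slc12a2 1.70-fold lower (median -0.35, adjusted p = 0.0295, and adjusted p = 0.544 with an estimated correlation), at -0.35 on day 7 and 0.02 between the other days. Atp4b had saturated spots in all 5 fed samples, and no difference can be given. Atp4a did not pass, at 0.03 ± 0.09 (SE, adjusted p = 0.833). The chief cell genes Cym and Cblif were 2.75-fold and 1.77-fold lower, and the mast cell tryptase Tpsab1 was 2.15-fold higher, although neither list passed.

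Cytosolic ribosomal proteins had 42 of 73 members higher and 3 lower, with Rpl13a 1.66-fold higher, a median of 0.21 that turned to -0.02 with quantile scaling of the channels, and an adjusted p of 3.14e-06 (adjusted p = 0.59 with an estimated correlation). The clock genes Per2 and Bmal1 were 2.32-fold and 1.92-fold lower, and Dbp, a clock output gene, was 1.70-fold higher, while the clock list did not pass. Stoml1 rose 4.76-fold, the inflammasome gene Mefv 4.38-fold, Hrasl1 3.79-fold, the zinc transporter Slc30a3 3.07-fold and perlecan (Hspg2) 2.78-fold. Slc12a7, Dnm2, Rasl12, Nck2 and the thioesterase Acot5 rose between 2.67-fold and 2.72-fold. Stoml1 differed by 2.29 on day 7 and 2.19 between the other days, and Mefv by 2.15 and 2.05. The ECL marker, immune, smooth muscle, exocytosis, immediate early and autophagy lists did not pass, and their median, mean and test direction differed in sign.

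In mucosa 18310 of 36218 features passed (9581 higher and 8729 lower), of which 329 were more than 2-fold higher and 120 more than 2-fold lower. Of 32 lists 10 passed with the preset correlation, and no list's count shifted by more than 2 when adjusted over the list alone. On the 3 arrays of day 7 the sign of the called differences was the same for 98.9%, 98.5% and 99.3% of them, and between the other days for 89.6%. The arrays of day 7 carried most of the weight in the fit that called these differences, so that their shares are no independent support. Treating channels as independent left 6168 features past the test.

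The third comparison tests whether fasting acted differently in ECL cells and in mucosa, through the difference of the 2 fasting effects. It passed for 9816 features, more positive in ECL cells for 5190 and more negative for 4626, with 6 ECL and 11 mucosal samples. Fed and fasted mucosa shared only day 7, which held no ECL sample, so that sample type and day cannot be fully told apart here. Genes with parietal cell expression were more positive in ECL cells: Clic6 by 1.83 ± 0.19 (SE), Kcnq1 by 1.74 ± 0.17 and Atp4a by 1.68 ± 0.16. Of 18 parietal cell markers 9 were more positive and 1 more negative (median 0.64, adjusted p = 1.68e-05, and adjusted p = 0.19 with an estimated correlation). Squamous genes were more negative in ECL cells, with Stfa3 at -4.41 ± 0.85, Csta at -4.14 ± 0.92, Spink5 at -2.80 ± 0.38, Krtdap at -2.39 ± 0.31 and Lgals7 at -2.30 ± 0.49 (SE). Of 14 squamous markers 11 were more negative and none more positive, with Sprr1a at -2.10 and Krt15 at -1.79 (median -1.09, adjusted p = 9.59e-10, and adjusted p = 0.0584 with an estimated correlation). The mucosal part of this difference came mostly from day 7, where the list median of mucosal fasting was 0.90 against 0.12 between the other days.

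For 2 lists the difference between ECL cells and mucosa held with an estimated correlation, at an adjusted p of 0.0273 for each. Other gastric endocrine markers had 7 of 10 members more negative in ECL cells, with Tph1 at -1.26, Gast at -1.18 and Sst at -1.13 (median -0.78, adjusted p = 1.68e-05). Heat shock genes had 11 of 18 members more positive, with Hsph1 at 1.44 and Dnaja1 at 1.26 (median 0.61, adjusted p = 1.86e-06). Slc18a1 was more negative in ECL cells by -1.04 ± 0.14 (SE), while Slc18a2 (0.03 ± 0.32, adjusted p = 0.955) and Cckbr (-0.36 ± 0.14, adjusted p = 0.0551) did not pass. For Hdc, Chga and Ghrl, saturated in all 3 fed ECL samples, and Atp4b, saturated in all 5 fed mucosal samples, this difference cannot be given. Among ECL cell markers 7 of 19 were more negative and 2 more positive (median -0.30, adjusted p = 0.0366, and adjusted p = 0.549 with an estimated correlation), a call that was lost with extraction day in the fit (median -0.18), as was that of the glucocorticoid response (0.0179). The feeding-related list had 7 of 30 members more negative, among them Cartpt at -1.14 (median -0.21, adjusted p = 0.0098, and adjusted p = 0.203 with an estimated correlation).

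The fatty acid oxidation list was more positive in ECL cells, with 17 of 35 members more positive and 1 more negative, among them Eci1 at 1.13 ± 0.27 (SE; median 0.43, adjusted p = 5.82e-05, and adjusted p = 0.271 with an estimated correlation). Oxidative phosphorylation had 17 of 40 members more positive, with Atp5f1a at 1.37 (median 0.34, adjusted p = 1.40e-06, and adjusted p = 0.271 with an estimated correlation). Glycolysis had 8 of 20 members more positive, with Pgk1 at 1.21 (median 0.25, adjusted p = 0.00787, and adjusted p = 0.255 with an estimated correlation). Sgk1 (1.70), the clock gene Per2 (1.56), Junb (1.24), Hspa5 (1.31) and Trib3 (0.81) were more positive, as were the cell cycle genes Aurka (1.16) and Pcna (1.15), Psma3 (0.69) and Ctsh (0.72). Cytosolic ribosomal proteins had 44 of 73 members more negative and 2 more positive, with Rpl13a at -0.90 (median -0.44, adjusted p = 5.43e-13, and adjusted p = 0.221 with an estimated correlation). The mucus regulator Clca1 was more positive in ECL cells by 2.05 ± 0.44 and the sulfotransferase Sult1c3 by 1.94 ± 0.31 (SE).

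Of 32 lists 18 passed in this comparison, and those not given above had medians between -0.19 and 0.42 and an adjusted p between 0.218 and 0.437 with an estimated correlation. Adjusted over the list alone, 49 ribosomal protein genes were more negative and 13 endoplasmic reticulum stress genes more positive, in place of 44 and 9, and no other list shifted by more than 2. The chief cell, exocytosis, lipogenesis and clock lists, which did not pass, differed in sign between median, mean and test. Leaving out ECL fasted sample 2 left 4554 features past the test, and treating channels as independent left 81.

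With fasting 1600 features were higher in both ECL cells and mucosa, against 1163.7 if calls were independent, and 2423 lower in both, against 1080.5. Opposite calls numbered 846 and 307, against 1060.2 and 1185.9. Among features changed more than 2-fold, 57 were higher in both and 27 lower in both. Across features, which are not independent replicates, the effects correlated at 0.37 (Pearson). Counts for independent calls ignore day effects, so a shared fasting response was not tested.

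**Figure D2:**
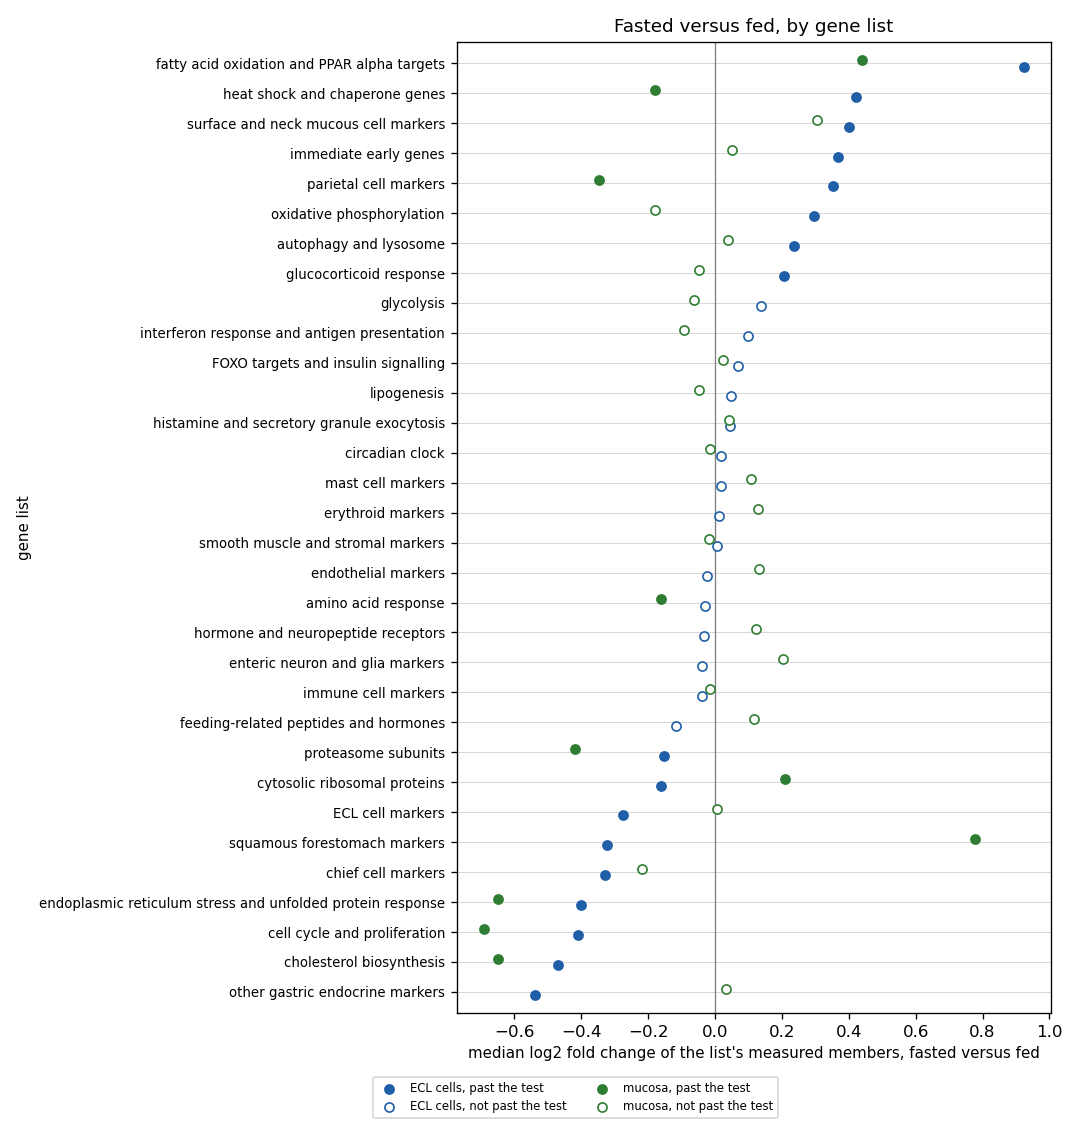
Median log2 difference between fasted and fed rats (horizontal axis) for each of the 32 gene lists in ECL cells and in mucosa, with filled points for lists past the test and open points for the others. Fatty acid oxidation lay at 0.92 in ECL cells and 0.44 in mucosa, and cell cycle genes at -0.41 and -0.69.

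The fourth comparison sets ECL against PC cells of fed rats, both purified. Genes of the histamine and peptide secretory pathway were higher in ECL cells. Slc18a2 was 62.8-fold higher (difference 5.97 ± 0.34, SE; 13.90 ± 0.24 against 7.65 ± 0.46, SD, n = 3 and 3) and Hdc at least 22.3-fold higher. Chromogranins followed, with Chgb at least 17.2-fold and Chga at least 5.19-fold higher, and so did the granule genes Cpe (35.0-fold), Scg5 (24.4-fold) and Resp18 (44.7-fold). Of 19 ECL cell markers 15 were higher, 1 lower and 3 not past the test (median 2.02, adjusted p = 5.05e-11, and adjusted p = 0.0758 with an estimated correlation). Other gastric endocrine markers had 7 of 10 members higher and none lower, with Ghrl at least 8.85-fold and Sst 7.34-fold higher (median 1.43, adjusted p = 3.67e-06), and this call held with an estimated correlation at an adjusted p of 0.0411. Exocytosis genes had 9 of 27 members higher and 4 lower, with Rab3c 12.7-fold higher (median 0.13, adjusted p = 0.024, and adjusted p = 0.0758 with an estimated correlation).

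Mitochondrial genes were lower in ECL cells than in PC cells. Oxidative phosphorylation had 35 of 40 members lower in ECL cells and none higher, with Ndufs1 4.47-fold and Uqcrc1 4.16-fold lower (median -1.21, adjusted p = 9.08e-16, and adjusted p = 0.0758 with an estimated correlation). Fatty acid oxidation had 26 of 35 members lower and none higher, with Acadvl 5.99-fold and Decr1 4.70-fold lower (median -0.98, adjusted p = 8.45e-12, and adjusted p = 0.0758 with an estimated correlation). Parietal cell markers had 14 of 18 members lower in ECL cells and 1 higher, with Clic6 6.40-fold and Kcnq1 4.37-fold lower and Cckar 31.0-fold higher (median -0.98, adjusted p = 6.91e-06, and adjusted p = 0.0758 with an estimated correlation). Atp4a was at least 1.36-fold lower in ECL cells. Cckbr did not pass, at -0.03 ± 0.14 (SE, adjusted p = 0.897), with group means in the opposite order, and Atp4b, saturated in all 3 PC samples, did not pass either (adjusted p = 0.456). Glycolysis had 12 of 20 members lower and 2 higher, with the muscle isoform Pfkm 4.12-fold lower and the neuronal isoform Eno2 6.94-fold higher (median -0.80, adjusted p = 0.00309, and adjusted p = 0.16 with an estimated correlation). Autophagy genes had 13 of 27 members lower and 2 higher, with Gabarapl1 2.85-fold lower (median -0.37, or -0.25 with extraction day in the fit), and proteasome subunits 10 of 24 lower and 1 higher, with Psma3 1.79-fold lower (median -0.24). Their adjusted p were 0.024 and 0.0318, and with an estimated correlation adjusted p = 0.242 and 0.425, and the proteasome call was lost with extraction day in the fit (-0.19).

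Amino acid supply, endoplasmic reticulum stress and immediate early genes were higher in ECL than in PC samples, while the heat shock list did not pass (7 of 18 higher, 4 lower, adjusted p = 0.0756). Amino acid response genes had 12 of 17 members higher and none lower, with the arginine transporter Slc7a1 23.5-fold and Phgdh 9.70-fold higher (median 1.09, adjusted p = 1.15e-08, and adjusted p = 0.0758 with an estimated correlation). Endoplasmic reticulum stress genes had 13 of 21 members higher and none lower, with Ero1b 11.7-fold and Herpud1 5.31-fold higher (median 1.02, adjusted p = 2.72e-07, and adjusted p = 0.0758 with an estimated correlation). Immediate early genes had 19 of 28 members higher and 1 lower, with Klf4 10.6-fold higher (median 0.90, adjusted p = 5.32e-08, and adjusted p = 0.0758 with an estimated correlation). Cholesterol biosynthesis had 14 of 25 members higher and 1 lower, with Msmo1 5.27-fold and Hmgcs1 4.73-fold higher (median 0.60, adjusted p = 2.96e-06, and adjusted p = 0.14 with an estimated correlation). Cell cycle genes had 17 of 33 members higher and 3 lower, with Cdk1 4.20-fold higher (median 0.47, adjusted p = 3.63e-06, and adjusted p = 0.0758 with an estimated correlation). Glucocorticoid response genes had 10 of 18 members higher and 2 lower, with Anxa1 12.4-fold higher (median 0.51), and ribosomal proteins 27 of 73 higher and none lower, with Rpl10a 2.54-fold higher (median 0.19). Their adjusted p were 0.00527 and 5.13e-04, and with an estimated correlation adjusted p = 0.0758 and 0.44.

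Further stomach cells' markers were higher in ECL than PC samples too (chief markers also over mucosa). Their part in the lists above was not tested. Chief cell markers had 8 of 10 members higher and none lower, with Chia at least 10.6-fold and Cblif 18-fold higher (median 2.83, adjusted p = 2.86e-08, and adjusted p = 0.0517 with an estimated correlation). Mucous cell markers had 6 of 13 members higher and 3 lower, with Tff2 4.78-fold higher (median 1.07, adjusted p = 0.024, and adjusted p = 0.336 with an estimated correlation), and the median turned to -0.0037 without PC sample 1 and the call was lost with extraction day in the fit (1.01). Squamous markers had 9 of 14 members higher and 2 lower, with Sprr1a 5.36-fold higher (median 1.06, or 0.39 with extraction day in the fit, adjusted p = 3.94e-04, and adjusted p = 0.156 with an estimated correlation). Smooth muscle and stromal markers had 7 of 17 members higher and 2 lower, with Col3a1 4.33-fold higher (median 0.34, adjusted p = 0.0278, and adjusted p = 0.336 with an estimated correlation). Feeding-related peptides had 11 of 30 members higher and 2 lower, with Nucb2 36.2-fold higher (median 0.09, mean 0.67, adjusted p = 0.00759, and adjusted p = 0.0758 with an estimated correlation), and the median turned to -0.0048 without the array term and was 0.14 with extraction day in the fit. The pancreatic-type genes Amy2a3 (38.4-fold) and Ptf1a (38.0-fold), the kallikreins Klk1b3 (78.0-fold) and Klk1c3 (56.3-fold), Mug1 (47.8-fold), Tmed6 (45.0-fold) and Specc1 (39.9-fold) were higher in ECL cells. Fbp1 (13.3-fold), Dusp13b (11.9-fold), Plppr4 (11.8-fold), Ugt2b7 (10.8-fold), Gp2 (10-fold), Sult1c3 (7.84-fold), Hsd17b6 (7.13-fold), Dst (6.21-fold) and Spp1 (6.12-fold) were lower.

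Between ECL and PC cells 13942 features passed (6389 higher and 7553 lower in ECL cells), of which 1599 were more than 2-fold higher and 1243 more than 2-fold lower. Of 32 lists 21 passed with the preset correlation, and FOXO targets and clock genes, which did not, differed in sign between median, mean and test. Adjusted over the list alone, 20 cell cycle genes were higher in place of 17, and no other list shifted by more than 2. No array and no day held both ECL and PC samples, so that this difference has no value within a batch, and 7073 features passed when channels were treated as independent. Through shared arrays the preparations were linked only by way of fed and fasted mucosa, which shared arrays on day 7 alone.

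**Figure D3:**
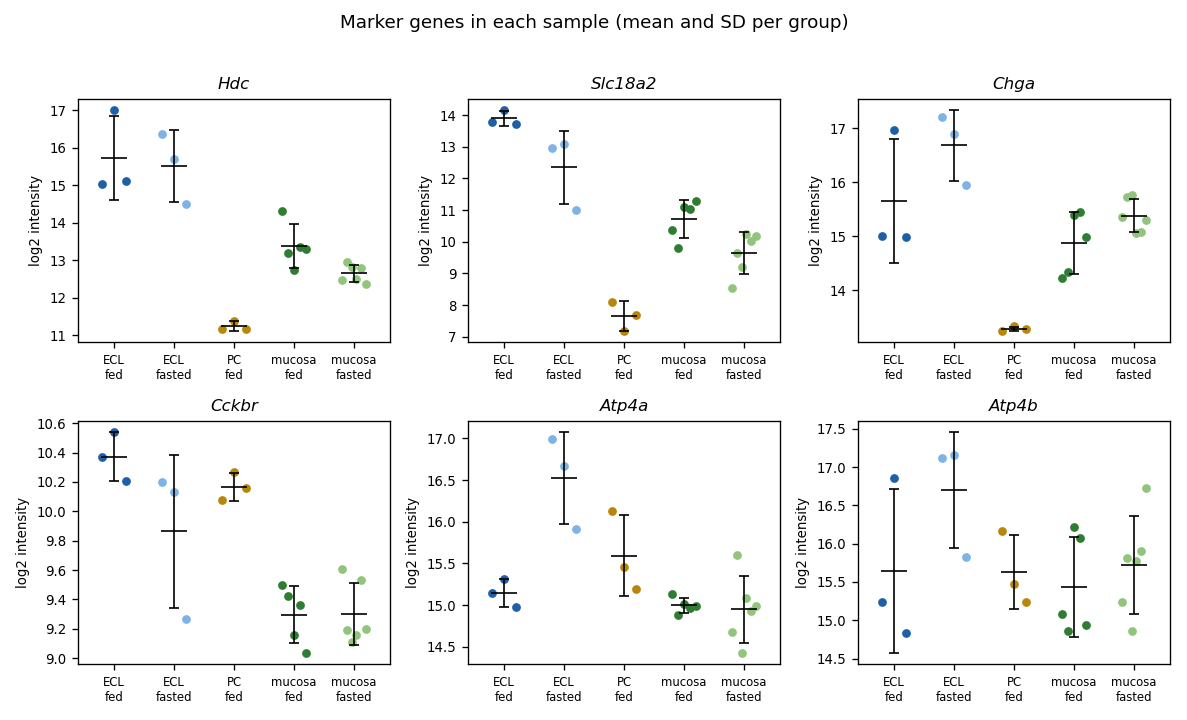
Log2 intensity (vertical axis) of marker genes of ECL and parietal cells in each sample of the 5 groups, with dots for samples and bars for the group mean and SD. Slc18a2 lay at 13.90 ± 0.24 in ECL cells and 7.65 ± 0.46 in PC cells of fed rats (SD, n = 3 and 3), with fed mucosa at 10.72 ± 0.61 (n = 5).

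The fifth comparison sets ECL cells against the whole mucosa of fed rats. ECL cell markers had 17 of 19 members higher, none lower and 2 not past the test (median 1.55, adjusted p = 5.37e-14). Slc18a2 was 12.2-fold higher (difference 3.60 ± 0.24, SE; 13.90 ± 0.24 against 10.72 ± 0.61, SD, n = 3 and 5), Hdc at least 5.05-fold and Chga at least 1.72-fold. Scg5 (11-fold), Scg3 (10.6-fold) and Cckbr (1.96-fold) were higher too. Other gastric endocrine markers had 8 of 10 members higher and none lower, with the ghrelin acyltransferase Mboat4 3.21-fold and Ghrl at least 1.66-fold higher (median 0.81, adjusted p = 3.33e-05). Both calls held with an estimated correlation, at an adjusted p of 0.0247 each.

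Stress-responsive and squamous genes were higher in ECL cells than in mucosa. Immediate early genes had 24 of 28 members higher and 1 lower, with Egr1 21.0-fold, Fos 15.5-fold and Jun at least 13.9-fold higher (median 1.82, adjusted p = 9.57e-17). Heat shock genes had 14 of 18 members higher and none lower, with Hspb1 11.6-fold and Hspa1a at least 21.1-fold higher (median 1.34, adjusted p = 4.37e-11). Squamous forestomach markers had 10 of 14 members higher and none lower, with Krt13 13.2-fold and Krt1 11.1-fold higher (median 1.70, adjusted p = 5.05e-10). Stfa3 was 65.8-fold, Csta 39.4-fold, Krtdap 19.7-fold, Dmkn 19.1-fold and Krt10 16-fold higher. With an estimated correlation these 3 lists held, at adjusted p of 0.0247 for immediate early and squamous genes and 0.00198 for heat shock genes. FOXO targets (12 of 26 higher, 2 lower, median 0.20, with Gadd45a 3.53-fold higher) and clock genes (6 of 18 higher, none lower, median 0.14, with Bhlhe41 3.90-fold and Nr1d1 1.97-fold higher) held as well, at 0.0247 each, with adjusted p of 0.00423 and 0.00475 at the preset correlation.

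Cell cycle genes were lower in ECL cells than in mucosa, with 25 of 33 members lower and 2 higher, Top2a 2.72-fold and Ccna2 2.38-fold lower (median -0.60, adjusted p = 1.49e-09), a call that held with an estimated correlation at an adjusted p of 0.0247. Mucous cell markers had 7 of 13 members lower and 1 higher, with Muc5ac 3.32-fold and Tff2 2.51-fold lower (median -0.92, adjusted p = 0.00128, and adjusted p = 0.187 with an estimated correlation). The globins Hbb-b1 (15.3-fold) and Hba-a3 (7.60-fold), Clca1 (6.80-fold), Rflnb (6.06-fold), the iodide transporter Slc5a5 (5.33-fold), Dok4 (5.13-fold), C3h15orf48 (4.80-fold), Fbp1 (4.78-fold), Wfdc1 (4.75-fold) and Igfbp3 (4.29-fold) were lower. Cholesterol biosynthesis had 12 of 25 members lower and 2 higher, with Cyp51 2.22-fold lower (median -0.24, adjusted p = 6.57e-04, and adjusted p = 0.268 with an estimated correlation). Parietal cell markers did not pass, with 6 of 18 members lower and 1, Cckar, 3.99-fold higher (median -0.08, adjusted p = 0.149). Atp4a did not pass either (0.23 ± 0.12, SE, adjusted p = 0.156), and for Atp4b, saturated in all 5 fed mucosal samples, no difference can be given.

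Chief cell markers had 6 of 10 members higher in ECL cells and none lower, with Cblif 3.91-fold and Cpb1 3.64-fold higher (median 0.87, adjusted p = 1.43e-04, and adjusted p = 0.0744 with an estimated correlation). Amino acid response genes had 10 of 17 members higher and 1 lower, with Slc7a1 5.59-fold higher (median 0.45, adjusted p = 1.39e-05, and adjusted p = 0.0926 with an estimated correlation). Endoplasmic reticulum stress genes had 11 of 21 members higher and 1 lower, with Herpud1 4.61-fold higher (median 0.29, adjusted p = 6.51e-04, and adjusted p = 0.17 with an estimated correlation). Glucocorticoid response genes had 12 of 18 members higher and 4 lower, with Dusp1 9.78-fold higher (median 0.33, adjusted p = 0.00339, and adjusted p = 0.066 with an estimated correlation). Feeding-related peptides had 13 of 30 members higher and 3 lower, with Reg1a 10.1-fold and Nucb2 4.78-fold higher (median 0.13, adjusted p = 0.00339, and adjusted p = 0.0638 with an estimated correlation). Receptors had 17 of 54 members higher and 6 lower, with Gipr 2.48-fold higher (median 0.10, adjusted p = 0.0209, and adjusted p = 0.263 with an estimated correlation). Ccn1 (51.2-fold), Amy2a3 (24.4-fold), Ggh (18.1-fold), Atf3 (16.9-fold), the neuronal gene Uchl1 (6.10-fold) and the glial gene Sox10 (2.94-fold) were also higher, although the neuron and glia list did not pass (3 of 12 higher, 1 lower, median 0.08, adjusted p = 0.13).

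Between ECL cells and mucosa of fed rats 14074 features passed (6889 higher and 7185 lower in ECL cells), of which 954 were more than 2-fold higher and 476 more than 2-fold lower. Of 32 lists 16 passed with the preset correlation and 8 with an estimated one, and no count shifted by more than 2 when adjusted over the list alone. The lipogenesis list, which did not pass, differed in sign between median and test. The sign was the same for 99.6% of the called features on array 1, the array that held a sample of each. Array 1 also carried much of the weight in the fit that called them, so that this share is no independent support. Leaving out mucosal fed sample 1 left 8743 features past the test and treating channels as independent left 4447.

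**Figure D4:**
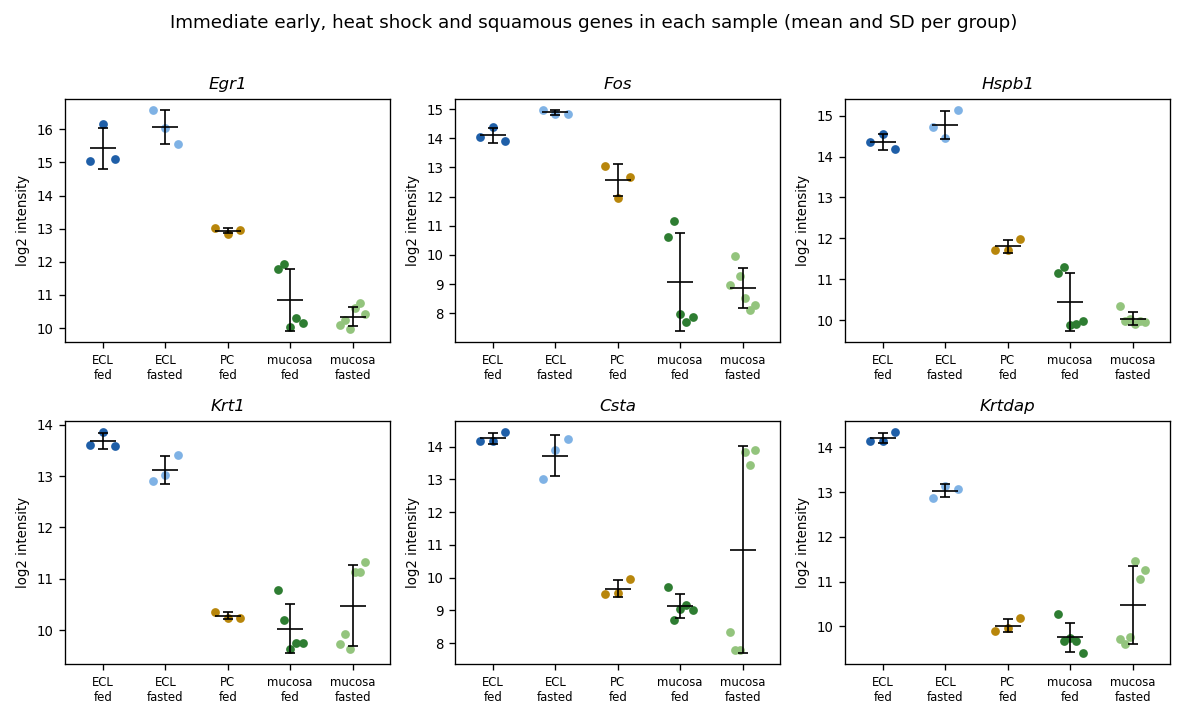
Log2 intensity (vertical axis) of 3 stress-responsive genes (Egr1, Fos, Hspb1) and 3 squamous genes (Krt1, Csta, Krtdap) in each sample of the 5 groups, with dots for samples and bars for the group mean and SD. Egr1 lay at 15.44 ± 0.62 in ECL cells and 10.84 ± 0.94 in mucosa of fed rats (SD, n = 3 and 5).

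The sixth comparison sets PC cells against the whole mucosa of fed rats. Mitochondrial genes were higher in PC cells: oxidative phosphorylation had 38 of 40 members higher and none lower, with Atp5f1a 4.47-fold and Ndufs1 3.78-fold higher (median 1.03, adjusted p = 2.06e-18, and adjusted p = 0.0861 with an estimated correlation). Fatty acid oxidation had 29 of 35 members higher and 2 lower, with Acsl1 6.71-fold and Eci1 5.93-fold higher (median 0.84, adjusted p = 2.63e-13, and adjusted p = 0.0861 with an estimated correlation). The fit linked PC cells to fed mucosa through the fasted and fed mucosa of day 7, where mucosal fasting raised this list. Between the other days the list was not higher in fasted mucosa, so the size of its difference here depends on day 7. Parietal cell markers had 15 of 18 members higher and 2 lower, with Kcnq1 4.44-fold (difference 2.15 ± 0.14, SE; 11.04 ± 0.46 against 8.13 ± 0.08, SD, n = 3 and 5), Slc4a2 2.94-fold and Clic6 2.92-fold higher (median 0.92, adjusted p = 2.19e-04, and adjusted p = 0.131 with an estimated correlation). Atp4a was at least 1.51-fold higher, Cckbr was 2.00-fold higher, and for Atp4b, saturated in all samples of both groups, no difference can be given.

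Genes of dividing, mucous, chief and endocrine cells were lower in PC cells than in mucosa. Cell cycle genes had 25 of 33 members lower and 2 higher, with Ccna2 7.68-fold and Cdk1 6.93-fold lower (median -1.02, adjusted p = 6.26e-14), and the call held with an estimated correlation at an adjusted p of 0.0155. Cholesterol biosynthesis had 20 of 25 members lower and 2 higher, with Hmgcs1 8.81-fold lower (median -1.08, adjusted p = 6.44e-12, and adjusted p = 0.0861 with an estimated correlation). Chief cell markers had 8 of 10 members lower and 1 higher, with Bhlha15 7.60-fold lower (median -1.72, adjusted p = 2.74e-05, and adjusted p = 0.0861 with an estimated correlation). Mucous cell markers had 9 of 13 members lower and 2 higher, with Tff2 12.0-fold and Muc5ac 11.4-fold lower (median -1.84, adjusted p = 1.24e-04, and adjusted p = 0.131 with an estimated correlation). ECL cell markers had 11 of 19 members lower and 4 higher, with Slc18a2 5.16-fold, Cpe 4.45-fold, Chgb 4.20-fold, Hdc 4.12-fold and Chga 3.80-fold lower (median -0.33, adjusted p = 0.0192, and adjusted p = 0.425 with an estimated correlation). Other endocrine markers had 5 of 10 members lower and 1 higher, with Ghrl 5.22-fold and Sst 4.24-fold lower (median -0.36, adjusted p = 0.0195, and adjusted p = 0.142 with an estimated correlation).

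Heat shock and immediate early genes were higher in PC cells too. Heat shock genes had 15 of 18 members higher and 1 lower, with Hspa1a 19.1-fold and Cryab 6.40-fold higher (median 0.97, adjusted p = 5.23e-07), and the call held with an estimated correlation at an adjusted p of 0.0155. Immediate early genes had 18 of 28 members higher and 3 lower, with Jun 11.2-fold, Fos 9.83-fold and Egr1 7.74-fold higher (median 0.68, adjusted p = 1.24e-04, and adjusted p = 0.196 with an estimated correlation). Autophagy genes had 20 of 27 members higher and 4 lower, with Gabarapl1 4.18-fold higher (median 0.44, adjusted p = 8.49e-05, and adjusted p = 0.0861 with an estimated correlation). Glycolysis had 12 of 20 members higher and 4 lower, with Pfkm 3.53-fold higher (median 0.47, adjusted p = 0.00139, and adjusted p = 0.16 with an estimated correlation), and proteasome subunits 15 of 24 higher and 2 lower, with Psma3 2.12-fold higher (median 0.30, adjusted p = 0.00179, and adjusted p = 0.276 with an estimated correlation). Lower lists were smooth muscle and stroma (10 of 17 lower, median -0.56, Col3a1 5.00-fold lower), the interferon response (12 of 23 lower, median -0.29, RT1-Da 2.38-fold lower), endoplasmic reticulum stress (9 of 21 lower, median -0.24, Ero1b 3.47-fold lower), the amino acid response (10 of 17 lower, median -0.24, Phgdh 5.62-fold lower) and ribosomal proteins (32 of 73 lower, median -0.14, Rpl4 1.79-fold lower). Their adjusted p were at most 0.00329, and with an estimated correlation adjusted p lay between 0.131 and 0.426.

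Outside the lists, Plppr4 (15.9-fold), Ugt2b7 (14.1-fold), Gp2 (11.2-fold), Dusp13b (11-fold) and Sult1c3 (7.41-fold) were higher in PC cells. Clca1 (54.8-fold), Slc5a5 (44.7-fold), Wfdc1 (40.4-fold), Hbb-b1 (25.0-fold), C3h15orf48 (23.3-fold), Rnase4 (21.7-fold), Adh7 (21.1-fold), Cotl1 (17.9-fold), Fgfbp1 (17.6-fold) and Pcsk6 (15.8-fold) were lower. Squamous markers had 12 of 14 members higher and none lower (median 0.59, adjusted p = 7.27e-05, and adjusted p = 0.131 with an estimated correlation), but their fitted differences departed from the group means. PC samples shared arrays with fasted mucosa and with no fed mucosa, so that the fit reached fed mucosa through the fasted and fed samples of day 7. Stfa3 was fitted at 5.34 ± 0.67 (SE) with means of 8.79 ± 0.34 in PC cells and 7.74 ± 0.48 in mucosa (SD, n = 3 and 5). Krt10 was fitted at 2.27 ± 0.57 (SE) with means of 8.37 ± 0.43 and 8.31 ± 1.78 (SD), and at -6e-04 when only PC cells and fed mucosa were fitted.

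Between PC cells and mucosa of fed rats 15814 features passed (8706 higher and 7108 lower in PC cells), of which 918 were more than 2-fold higher and 1089 more than 2-fold lower. Of 32 lists 20 passed with the preset correlation and 2 with an estimated one, and no count shifted by more than 2 when adjusted over the list alone. The neuron and glia, receptor and feeding-related lists, which did not pass, differed in sign between median, mean and test. The sign of the fitted difference was that of the group means for 93.63% of the called features, compared with 98.52% to 99.85% in the other comparisons of 2 groups. When only the 2 groups were fitted 7273 features passed, and no array or day held both PC cells and fed mucosa.

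**Figure D5:**
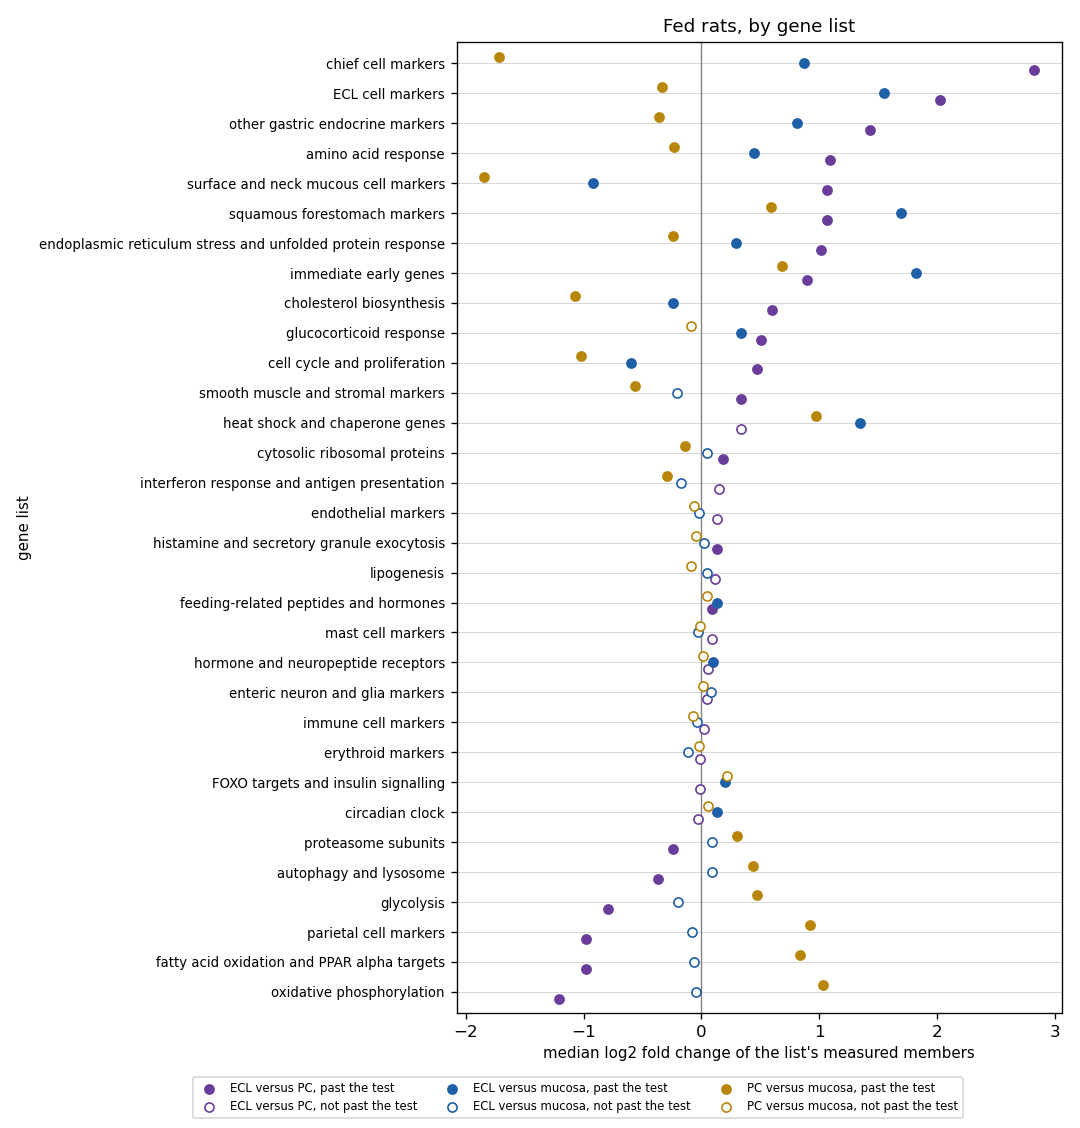
Median log2 difference (horizontal axis) of each of the 32 gene lists between ECL cells, PC cells and mucosa of fed rats, with filled points for lists past the test and open points for the others. Oxidative phosphorylation lay at -1.21 in ECL against PC cells and at 1.03 in PC cells against mucosa, and ECL cell markers at 2.02 in ECL against PC cells.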

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

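The 9 tests of explanations in this part were all chosen after the result they concern was seen, while the counts over other splits of the samples and the tests of single samples and of group differences were planned.

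Of 223 values tested, 5 had a sample that stood apart from the others, which is fewer than the 1 in 20 that chance alone gives. They are listed here and not read as results. In mucosa fasted sample 1 Ckap2 was at 7.793, with a median of 8.325 in the other samples of its group. The same sample had a mean of 8.845 for mast cell markers, against a median of 8.605 in the others, and a mean correlation with its group of 0.953, against 0.9707. In mucosa fasted sample 2 Sst was at 12.86, against a median of 13.95 in the others, and feeding-related peptides averaged 9.077, against 9.206.

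The fitted fasting effects in ECL cells and in mucosa differed for 9816 features by the test of the difference itself. No ECL sample was extracted on day 7, the only day with fed and fasted mucosa together. Sample type and day can therefore not be fully told apart in this difference. Among the genes with the largest differences were Clca1 (2.05), Sult1c3 (1.94), Clic6 (1.83) and Kcnq1 (1.74) on the side of ECL cells, and Stfa3 (-4.41), Csta (-4.14), Spink5 (-2.80), Krtdap (-2.39) and Lgals7 (-2.30) on the other. List medians of this difference were -0.30 for ECL markers, 0.64 for parietal markers, -0.78 for other endocrine markers, -1.09 for squamous markers, -0.19 for receptors, -0.21 for feeding-related peptides, 0.43 for fatty acid oxidation, 0.25 for glycolysis, 0.34 for oxidative phosphorylation and 0.29 for the glucocorticoid response. They were 0.42 for immediate early genes, 0.61 for heat shock genes, 0.345 for endoplasmic reticulum stress, 0.24 for the amino acid response, 0.20 for the cell cycle, -0.44 for ribosomal proteins, 0.31 for the proteasome and 0.25 for autophagy.

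The channels that the labels do not describe carried signal. On the array of ECL fed sample 1, 93.47% of spots in the second channel were well above background, and on the array of ECL fasted sample 3, 95.7%.

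Other splits of the same samples were counted for each comparison. For mucosal fasting and for the difference of both fasting effects, 100 splits of 462 and 9240 possible ones were counted. They were the real split and others drawn at random, and splits that were not drawn may call more features. For mucosal fasting 1 of 100 splits, the real one, called 18310 features and the highest other called 14429. For the difference of both fasting effects it was 1 of 100, with 9816 against 9517. For ECL cells against mucosa it was 1 of 56, with 14074 against 10817 for the split of mucosal fed samples 1, 2 and 5 from the rest, and for PC cells against mucosa 1 of 56, with 15814 against 11900 for the split of mucosal fed samples 3, 4 and 5, those of day 7, from the rest. These splits moved samples freely over arrays and days, while samples of 1 array were alike, and splits that followed arrays or days called many features. The samples were therefore not exchangeable, and whether chance can be excluded is left open. For ECL fasting the 10 splits are too few, with 8882 features for 1 of them, the real one, and 5202 for the highest other, and so they are for ECL against PC cells, with 13942 for 1 of 10 and 56 for the highest other.

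Fatty acid oxidation genes were higher in ECL cells of fasted rats, with 26 of 35 members higher and a median of 0.92. Array 4 alone is excluded as the source, since the median was 0.88 on day 1, from other arrays, with 30 members above 0. Parietal cells in the ECL preparations of fasted rats stay open, because their expected share was computed from PC cells of fed rats and no PC sample of fasted rats was analysed. With that assumed profile PC cells would make up 92.15%, with ECL markers changed by -1.71 and parietal markers by 0.92, whereas they changed by -0.28 and 0.35, and 10 of the 35 members lay above both the ECL and the PC level of fed rats. A rise shared with the mucosa is also open, with a mucosal median of 0.49 on day 7 (0.42 to 0.52 over its 3 arrays) but -0.18 between the other days, so that a fasting response of the ECL cells themselves is a hypothesis.

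Squamous genes were higher in ECL cells than in mucosa of fed rats (median 1.70) and moved apart with fasting. The difference of their fasting effects did not pass camera with an estimated correlation (adjusted p = 0.0584). Its mucosal part came mostly from day 7. A single ECL sample as the source is excluded, since the lowest of the 3 fed ECL samples lay 1.56 above mucosa. Squamous cells in the ECL preparations may contribute, but a second list of 32 other squamous genes had a median of 0.26, with 14 members higher and 4 lower (P = 1.89e-04, and 0.0394 with an estimated correlation), a list that passed but lay below 0.5 of the first median, which decides neither way. Its median in fasted against fed mucosa was 0.16 (P = 0.00244, and 0.0864 with an estimated correlation), and so squamous cells in differing amounts in the mucosa stay open. No biological explanation was tested.

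Immediate early and heat shock genes were higher in both purified preparations than in mucosa, with the lowest of the 4 medians, immediate early genes in PC cells, at 0.68 (adjusted p = 0.196 with an estimated correlation). The choice among the scalings used is excluded as the cause, since the lowest of these medians over the scaling alternatives was 0.60. All of these scalings set the overall level of channels alike, within or between arrays. They therefore cannot exclude a global difference in level between purified cells and mucosa. Cell isolation is in line with the value of 0.68, but isolation and cell type cannot be told apart here, because every purified sample was isolated and no mucosal sample was. The same lists were also higher in fasted ECL cells than in fasted mucosa, with medians of 2.55 and 2.03.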

How the results depend on the processing

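The alternatives restricted to day 7, averaging the similar dye-swapped arrays or leaving out the 2 ECL samples with an undescribed second channel were chosen after seeing the data, and the others were planned. Of 317 gene results named, 224 kept direction and side of the threshold under every alternative and 14 reversed under at least 1. Of 102 list calls, 14 were the same under every alternative and 4 reversed under at least 1. With an estimated correlation 14 of the 102 list calls passed. The cause was not tested for any change below unless it is named.

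Without the array block 727 features passed for ECL fasting, 6168 for mucosal fasting, 81 for the difference of both, 7073 for ECL against PC cells, 4447 for ECL cells against mucosa and 7137 for PC cells against mucosa. By construction this fit ignores that 2 channels of an array are alike. With only the compared groups in the fit 3437 features passed for ECL fasting, 19765 for mucosal fasting, 10666 for the difference of both, 7079 for ECL against PC cells, 10786 for ECL cells against mucosa and 7273 for PC cells against mucosa.

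With the replicate block, which treats samples with 1 number as paired, 4122 features passed for ECL fasting, 10736 for mucosal fasting and 3486 for the difference of both. For the 3 comparisons of cell types this block could not be estimated.

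With extraction day in the fit 6 list calls were lost: mucous markers in ECL fasting (median 0.26) and in ECL against PC cells (1.01), heat shock genes in mucosal fasting (-0.16), ECL markers (-0.18) and the glucocorticoid response (0.0179) in the difference of both, and proteasome subunits in ECL against PC cells (-0.19). With the same term 5 lists passed that had not: glycolysis in ECL fasting (0.17), oxidative phosphorylation in mucosal fasting (-0.18), cholesterol biosynthesis in the difference of both (0.17), the interferon response in ECL cells against mucosa (-0.18) and FOXO targets in PC cells against mucosa (0.23). Of the 102 list calls the array as a fixed block lost 12, no array block 12, only compared groups and the deposited values 7 each, processed signals 6, median scaling 5, quantile scaling 3, sample weights 3 and no dye term 2. The replicate block lost 9 of the 45 calls it covered, and leaving out the 2 ECL samples lost 7 of 35. Over all fits with a single sample left out, a list call was lost 34 times and kept 897 times.

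Leaving out 1 sample gave 3621 to 8728 features for ECL fasting (3621 without ECL fasted 2 and 3809 without ECL fed 3), 14027 to 18591 for mucosal fasting, and 4554 to 10091 for the difference of both (4554 without ECL fasted 2, 5417 without ECL fed 3 and 6371 without mucosa fed 1). It gave 10889 to 14348 for ECL against PC cells, 8743 to 14108 for ECL cells against mucosa (8743 without mucosa fed 1 and 8807 without ECL fed 2) and 12804 to 15831 for PC cells against mucosa. By construction, leaving out ECL fasted 2 or ECL fed 3 breaks up the 1 array that holds ECL cells of both food groups. Leaving out mucosa fasted 1 gave 17972 features for mucosal fasting. The added alternatives gave 23319 features for mucosal fasting on day 7, 15584 with the dye-swapped arrays averaged, and 8592 for ECL fasting and 9774 for the difference without the 2 ECL samples.

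List medians that reversed were oxidative phosphorylation in ECL fasting (-0.0737, only compared groups), ribosomal proteins in mucosal fasting (-0.0238, quantile scaling), mucous markers in ECL against PC cells (-0.0037 without PC sample 1, the low end of a leave-one-out range that reached 1.477 without PC sample 2) and feeding-related peptides in the same comparison (-0.0048 without array block and with only compared groups, -0.0241 with sample weights).

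Values below for Hdc and Chga in ECL fasting, for Chga in the difference of both and for Atp4b throughout involve a group saturated in every sample, so they are output of the fits and show neither a difference nor its direction. In ECL fasting Hdc reversed to -0.0849 (quantile scaling), -0.0415 (deposited table), -0.29 (no array block) and -0.93 (only compared groups), and Chga to -0.16 (quantile scaling). In mucosal fasting Chga reversed to -0.15 (quantile), -0.0513 (array fixed), -0.0495 (day block) and -0.0103 (day 7 only), Cckbr to -0.0073 (no array block), Atp4a to -0.29 (quantile), -0.0593 (no array block), -0.0173 (array fixed), -0.0117 (replicate block), -0.0165 (day block) and -0.015 (only compared groups), and Atp4b to -0.0921 (quantile). In the difference of both, Slc18a2 reversed to -0.56 (no array block) and -0.18 (replicate block) and ranged from -0.2479 to 0.3252 on leaving out single samples, Chga reversed to -0.0143 (quantile), and Atp4b ranged from -0.0558 without ECL fed 3 to 1.1623 without ECL fed 2.

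In ECL against PC cells Cckbr reversed to 0.0241 (no dye term), 0.21 (no array block and only compared groups) and 0.0461 (sample weights), and ranged from -0.1059 without PC 1 to 0.0688 without ECL fed 3, with 0.0533 without PC 3. Atp4b reversed to 0.089 (no dye term) and 0.0141 (no array block and only compared groups), and ranged from -1.3392 without PC 1 to 0.0647 without ECL fed 3. In ECL cells against mucosa Atp4a reversed to -0.0111 (quantile) and Atp4b to -0.17 (quantile), with a range from -0.0469 without ECL fed 2 to 1.1002 without ECL fed 3, and in PC cells against mucosa Krt10 reversed to -6e-04 (only compared groups).

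With other scaling the median of all features moved most for ECL against PC cells, from -0.03 to -0.13 with the deposited table, and the share of called features that were higher moved most for ECL cells against mucosa, from 48.95% to 40.71% with the same table. Processed signals in place of normexp gave 1490 features called and more than 2-fold apart in ECL fasting against 431, 1151 in mucosal fasting against 449, 1788 in the difference of both against 530, 4832 in ECL against PC cells against 2842, 2872 in ECL cells against mucosa against 1430 and 3350 in PC cells against mucosa against 2007. Signal over background limits dim probes only in part, as 92.37% to 97.39% of spots were well above background, while for Hdc, Chga, Chgb, Ghrl, Atp4a, Atp4b, Chia, Hbb, Jun, Hspa1a and Rplp1 a fold in at least 1 comparison is a bound.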

Other observations

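Several further genes of squamous epithelia, picked after the first squamous list had been seen, were abundant in ECL cells of fed rats. The kallikrein Klk8 had a mean log2 intensity of 12.02 in ECL cells and 8.55 in mucosa of fed rats, the gap junction gene Gjb2 11.96 and 8.63, and the desmosomal gene Dsg1 9.19 and 6.49 (n = 3 and 5). In ECL cells of fasted rats Klk8 was at 11.56, Gjb2 at 10.96 and Dsg1 at 8.61 (n = 3). S100a8 in the same list did not pass the test between ECL cells and mucosa of fed rats (8.04 and 8.08), and S100a9 was lower in ECL cells (7.39 and 7.49). Across the list, 14 of 32 genes were higher and 4 lower in ECL cells than in mucosa of fed rats, and 3 higher and 10 lower in ECL cells of fasted than of fed rats.

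Against fasted mucosa, ECL cells of fasted rats had 23 immediate early genes and 14 heat shock genes higher, and 10 squamous markers higher with a median of 0.39.

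The channel beside ECL fed sample 1 had mean Pearson correlations across features of 0.9525 with ECL fed, 0.9474 with ECL fasted, 0.9517 with PC, 0.9416 with mucosa fed and 0.9095 with mucosa fasted samples of the same dye, and the channel beside ECL fasted sample 3 had 0.9346, 0.958, 0.9586, 0.9219 and 0.911. Features are not independent replicates. Among mucosal samples the closest were fed 3 and 5 (0.9928) and fasted 4 and 6 (0.9924), which lie on 2 arrays with opposite dyes. The labels do not say whether these share RNA.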
